A study of Rattus norvegicus with 6 samples.

How the data were processed

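RNA from trigeminal ganglia of 6 rat samples, 3 with constriction of the infraorbital nerve and 3 with the same constriction and the light-driven gel conduit, was measured by RNA-seq. Total RNA was extracted with TRIzol, mRNA was purified and libraries were sequenced in pairs of reads on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name fastp, HISAT2, HTSeq, SAMtools and DESeq2 and the rat genome build mRatBN7.2; versions, the annotation and the strand setting are not given in the sources used here. The deposited counts are whole numbers of reads per gene symbol for 29884 genes, with no scaling. The deposited FPKM values are those counts per kilobase of gene length, scaled by the total counts of the library: over 21964 genes checked, count and FPKM gave the same length in every library, so they are no independent measurement. Of the symbols, 26249 matched a RefSeq symbol of the later build GRCr8, used for names only, and 175 matched a synonym only.

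Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Groups came from the sample titles, and the only comparison was conduit against injury. Genes were kept by edgeR's filterByExpr with its minimum of 10 counts, which left 16478 genes; libraries were scaled by TMM, and groups were compared by the robust quasi-likelihood F test with no covariate, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The common biological coefficient of variation was 0.295, with 4 residual degrees of freedom. The 39 gene lists were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, which held for 37; the pituitary and sex-linked lists had fewer. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the lists. With 3 libraries against 3, an exact permutation test of a single value can give no p under 0.1. Log2 CPM per library used a prior count of 2, and values under 3 counts are treated as at the floor. The labels do not say that each sample is a separate animal, so p-values of single genes measure the spread between samples. Camera's p-values at the preset correlation weigh list members against the other genes. They assume a correlation of 0.01 between members, so they do not measure how much a list's level varies between samples.

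The comparison, tests, gene lists, naming rule and a first set of other settings were fixed before the data were examined. The rule named up to 8 genes per direction past the threshold with a mean log2 CPM of at least 1, no overlap between groups and a symbol that is not a clone-type name, or otherwise the 5 genes per direction with the smallest p. It also named up to 4 members per list with the smallest p, and Atf3, Gal, Ppargc1a, Tfam, Hif1a, Vegfa, Hmox1, Sod2, Il1b, Scn9a and Calca; some genes that the rule names are not reported here. Because no gene with an eligible symbol passed, the fallback was used in both directions; the conditions on expression, overlap and symbol were applied to it too, a reading of the rule made after the data were seen. Other genes given per library (Mki67, Prl, Acta1, Myh4, Mobp, Adipoq and RT1 genes) were chosen after their values were seen. That first set held other scalings (RLE, upper quartile) and filters, DESeq2, limma-voom, the non-robust fit, limma on log2 FPKM with a pseudocount of 1 or 0.1, the replicate number, batch or day in the fit, a fold of at least 2, each library left out and batch 2 alone. Chosen after seeing the data were leaving out injury sample 1 with conduit sample 2, leaving out injury samples 2 and 3, voom with sample weights, testing without the genes of the tissue lists, and the lists within batch 2.

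The gene and list tests were tested on simulated data, with counts drawn for the real genes at the real depths of 40.2 M to 41.9 M counts and 200 genes changed. For conduit against injury, edgeR on 16247 genes recovered 38% of 100 genes changed 2-fold and 71% of 100 changed 4-fold. It made 117 calls, 8 of them among the 16031 unchanged genes left after its filter. DESeq2 on 16470 genes recovered 58% and 79% and made 210 calls, 71 of them among 16250 unchanged genes. Limma-voom on 16247 genes recovered 31% and 68% and made 105 calls, 6 of them on unchanged genes. A log2 shift of 0.40 given to the myelin list was estimated at 0.41 (camera adjusted p = 4.3e-07), and 1 other list of 37 was called. Genes were drawn independently of each other there, whereas the correlation estimated in the data was 0.38 for myelin and 0.75 for interferon members. The simulation therefore cannot show how often camera at the preset correlation calls unshifted lists in these data.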

Results

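Trigeminal ganglia, which house the cell bodies of the sensory neurons of the face, were profiled by RNA-seq in 6 rat samples. The 3 injury samples came from rats whose infraorbital nerve, a branch supplying the face, had been chronically constricted, a model of trigeminal neuralgia. The 3 conduit samples came from rats that had the same constriction and were treated with a light-driven bioactive gel in a nerve conduit. The libraries held 40.2 M to 41.9 M counts each, and between 19894 and 21061 genes had at least 1 count. The labels place the injury samples at days 14, 15 and 16 and the conduit samples at days 17, 18 and 19; they rise by 1 per sample in label order, and whether they are true sampling days is not known. They place injury samples 1 and 2 in batch 1, injury sample 3 and conduit sample 1 in batch 2, and conduit samples 2 and 3 in batch 3. All libraries expressed Y-linked genes, with Eif2s3y between 78.9 and 83.9 CPM, and Xist did not exceed 0.0502 CPM. Values per gene are TMM-scaled CPM, as mean ± SD over n = 3 libraries per group, and fold changes are conduit over injury on the log2 scale.

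The comparison asked which transcripts of the ganglion differed between treated and untreated constriction. The study's title points to mitochondrial function. Red blood cell genes were lower in all 3 conduit libraries: the 12 tested erythroid genes had a median log2 fold change of -3.40, and Hba-a2, an alpha-globin gene, was 1082 ± 68.1 CPM in injury and 162 ± 59.3 in conduit. Interferon-stimulated genes were higher, with a median of 1.52 over 30 genes, and genes of peripheral myelin were higher by a median of 0.40 over 20 genes. Genes of the respiratory chain and of pain sensing had list medians between -0.06 and 0.21. A single gene passed the test over all 16478 genes tested, and it was lower in conduit.

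That gene was RGD1563601, whose function is not given in the sources used here and which the naming rule left out, so it was chosen after its values were seen. It was 26.8 ± 2.26 CPM in injury and 4.65 ± 0.967 in conduit (log2 fold change -2.53, SE 0.17; edgeR quasi-likelihood adjusted p = 0.0357), with all 3 conduit libraries below all 3 injury libraries. The call was lost without injury sample 2 (edgeR adjusted p = 0.113) and without conduit sample 3 (edgeR adjusted p = 0.137), and its adjusted p ranged from 2.0e-34 to 0.99992 over the alternatives. Without injury sample 1 edgeR called 38 genes, 37 of them lower. Without injury sample 3 it called 35, 31 of them higher. Without conduit sample 1 it called 6, and without conduit sample 3 it called 0, with 1215 at an unadjusted p under 0.05. With all libraries 882 genes had an unadjusted edgeR p under 0.05, 493 higher and 389 lower in conduit, against 823.9 that chance gives. The libraries of the groups did not overlap for 9.63% of the tested genes, where chance gives 10%. DESeq2 called 208 genes on the same counts, 111 higher and 97 lower, and limma-voom called 1. In the simulation 71 of 210 DESeq2 calls fell on unchanged genes. The simulation drew only genes past edgeR's filter, whereas DESeq2 tested 23447 genes in the data. That share therefore need not hold for the 208 calls.

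Erythroid genes fell as a list in conduit (camera adjusted p = 1.7e-55; adjusted p = 0.0246 with an estimated correlation). All 12 tested members were lower in every conduit library than in every injury library, and all 12 passed when adjusted over the list alone, while over all genes edgeR called 0 of them, with all 12 at an unadjusted p under 0.05, and DESeq2 called 11. Hba-a1 was 2813 ± 299.6 CPM in injury and 404 ± 194 in conduit, and Alas2, the first enzyme of heme synthesis in red cell precursors, was 67.9 ± 19.8 CPM in injury and 7.06 ± 3.498 in conduit. Hbb-b2, a beta-globin gene outside the list, was 6.67 ± 0.89 CPM in injury and 0.899 ± 0.197 in conduit (edgeR adjusted p = 0.0585). Hba-a3 was at 99.7, 27.4 and 31.2 CPM in the injury libraries, from 4010, 1158 and 1293 counts, and had 1 count over the 3 conduit libraries. It ranks below the list's median at any such level. Copies among the alpha-globin genes, and among the beta-globin genes, can be near-identical, so reads can be split between them and each copy's level is uncertain. Within batch 2, which holds 1 library of each group, the erythroid median was -3.17. Alox15, a lipoxygenase, was 23.4 ± 5.87 CPM in injury and 1.49 ± 0.668 in conduit (edgeR adjusted p = 0.0585), and Dsp, a desmosome protein, was 7.94 ± 0.47 CPM in injury and 0.866 ± 0.308 in conduit (edgeR adjusted p = 0.0585).

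**Figure D1:**
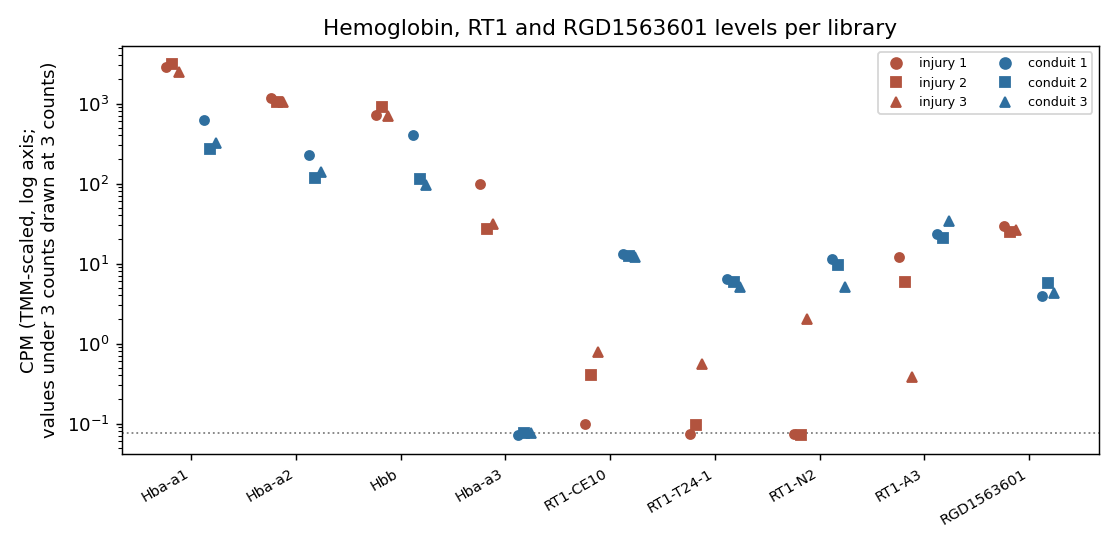
CPM of 4 hemoglobin genes, 4 RT1 genes and RGD1563601 in each library on a log axis, with values under 3 counts drawn at the level of 3 counts and a dotted line at the highest such level. Each point is 1 library; RGD1563601 and the hemoglobin genes lie lower and the RT1 genes, of which all but RT1-CE10 were picked for their values, higher in all 3 conduit libraries, with RT1-CE10 at 11.9 to 13.2 CPM in conduit.

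The proliferation, neutrophil and mast cell, and cartilage and bone lists also fell, with their highest mean levels in injury samples 2 and 3. The proliferation list had a median log2 fold change of -1.004 (camera adjusted p = 1.5e-17; adjusted p = 0.648 with an estimated correlation), with 25 of 25 members lower. Mki67, a marker of dividing cells, stood at 43.8 and 28.9 CPM in injury samples 2 and 3, at 3.51 in injury sample 1 and at 3.16 to 5.74 in conduit. The neutrophil and mast cell list had a median of -3.53 (camera adjusted p = 3.9e-07; adjusted p = 0.672 with an estimated correlation), and 13 of 18 members were lower, 7 of them in every conduit library against every injury library, injury sample 1 included. Over all genes edgeR called 0 of these 18, with 9 lower at an unadjusted p under 0.05, and DESeq2 called 6 lower. S100a8, an abundant neutrophil protein, was 13.3, 154 and 33.1 CPM in injury and 2.46 to 6.38 in conduit. The cartilage and bone list had a median of -1.50 (camera adjusted p = 6.8e-06; adjusted p = 0.648 with an estimated correlation). Ibsp, bone sialoprotein, was 8.602, 55.96 and 34.2 CPM in injury and 3.57 to 6.83 in conduit. Within batch 2 the proliferation, neutrophil and bone medians were -0.85, -3.42 and -0.78. Without injury sample 2 the proliferation and neutrophil medians were -0.57 and -1.62, and without injury sample 3 the bone median was -0.98, all still called. Without injury samples 2 and 3 the 3 medians were 0.09, -0.25 and -0.02, and none of these lists was called.

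Interferon response genes rose as a list in conduit (camera adjusted p = 7.0e-53; adjusted p = 0.383 with an estimated correlation). All 30 members were higher, 24 of them with no overlap between the libraries of the groups. Of these genes 17 passed when adjusted over the list alone. Over all genes edgeR called 0 of them, with 22 at an unadjusted p under 0.05, and DESeq2 called 10. Mx1, an antiviral GTPase, was 26.2 ± 16.8 CPM in injury and 133 ± 55.01 in conduit. Bst2, which tethers virus particles to the cell, was 24.3 ± 10.6 CPM in injury and 70.6 ± 8.43 in conduit, and Ifi35, an interferon-induced gene outside the list, was 11.4 ± 1.32 CPM in injury and 22.3 ± 0.797 in conduit (edgeR adjusted p = 0.121). Injury sample 3 lay above injury samples 1 and 2, by a median of 1.46 on the log2 scale, and within batch 2 conduit sample 1 exceeded it by a median of 1.08. Without injury sample 3 the median log2 fold change was 2.37. RT1-CE10, a class I major histocompatibility gene, was 0.432 ± 0.349 CPM in injury and 12.5 ± 0.613 in conduit (edgeR adjusted p = 0.121). RT1 genes share sequence, so reads may be divided among copies and the level is uncertain. Among injury libraries RT1-CE10 was highest in injury sample 3, at 0.795 CPM. RT1-A3, picked for its values, was lowest there, at 12.1, 5.84 and 0.386 CPM in injury and 21.1 to 33.6 in conduit. Whether the RT1 levels follow the interferon genes, a difference in genotype or shared reads was not tested. Serpina3n, an acute-phase protease inhibitor, was 0.771 ± 0.226 CPM in injury and 12.4 ± 6.32 in conduit (edgeR adjusted p = 0.0991). The macrophage list had a median of 0.16 (camera adjusted p = 0.0684; within batch 2 0.95) and the cytokine list -0.01 (camera adjusted p = 0.528; within batch 2 0.33). Camera at the preset correlation called the macrophage list higher in 10 of 19 tested alternatives. With 1 library left out it was called without injury sample 2 (0.38), conduit sample 2 (0.30) or conduit sample 3 (0.42). Its median was -0.26 without conduit sample 1. The cytokine list was called in 6 of 19 tested alternatives, among them without injury sample 2 (0.13). Its median ranged from -0.25 to 0.13 with each library left out. The chemokine Cxcl9 was 2.71 ± 0.396 CPM in injury and 5.796 ± 0.109 in conduit and Il1b was 1.54 ± 0.85 CPM in injury and 1.17 ± 0.796 in conduit.

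**Figure D2:**
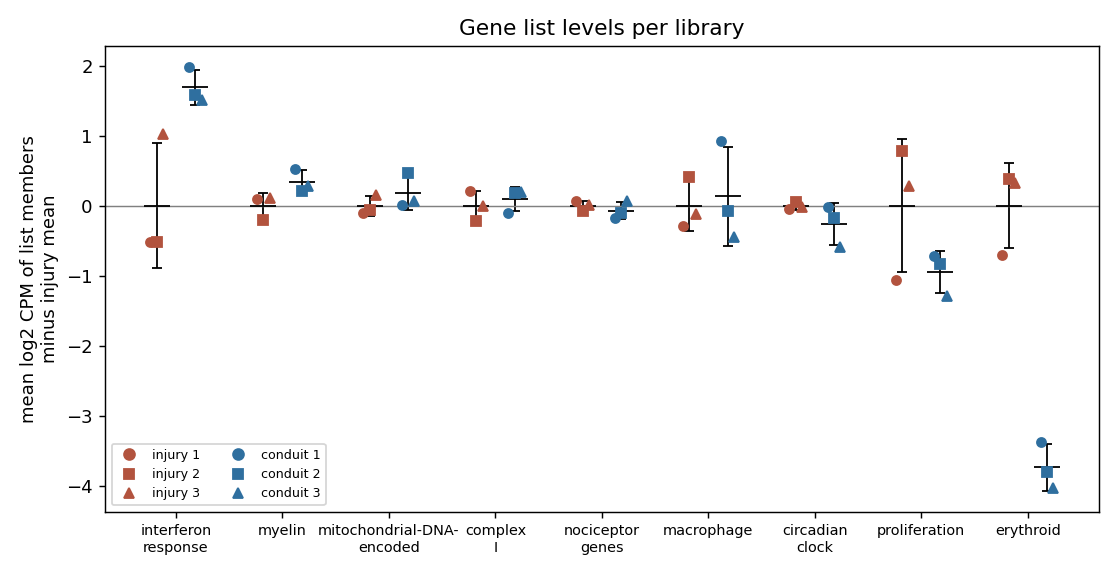
Mean log2 CPM of the tested members of 9 gene lists in each library, minus the injury mean of that list. Points are the 3 libraries of each group and black bars give the group mean ± SD; the interferon and myelin lists lie higher in every conduit library, the erythroid list lies lower in every conduit library, and the groups overlap for the other lists.

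Genes of peripheral myelin rose as a list (camera adjusted p = 9.8e-16; adjusted p = 0.423 with an estimated correlation). Of 20 members 18 were higher, 11 with no overlap between libraries, and 11 passed when adjusted over the list alone. Over all genes edgeR called 0 of them, with 12 higher at an unadjusted p under 0.05, and DESeq2 called 7 higher. The cause of this rise was not tested. Pmp22, a protein of compact myelin, was 5853 ± 164 CPM in injury and 8615 ± 524 in conduit. Egr2, the transcription factor that drives myelination, was 39.2 ± 4.08 CPM in injury and 62.9 ± 3.102 in conduit. Within batch 2 the myelin median was 0.37. The satellite glia list rose by a smaller median of 0.14 (camera adjusted p = 0.0162; adjusted p = 0.829 with an estimated correlation), a call lost without injury sample 1 (median 0.10), injury sample 2 (0.06) or conduit sample 1 (-0.04) and with a median of 0.25 without conduit sample 2. Within batch 2 it was 0.23. Repair Schwann cell genes had a median of -0.01 (camera adjusted p = 0.859). Faxdc2 was 45.1 ± 2.62 CPM in injury and 69.9 ± 3.601 in conduit (edgeR adjusted p = 0.144), and Serpinh1, the collagen chaperone, was 253 ± 13.7 CPM in injury and 392 ± 18.5 in conduit (edgeR adjusted p = 0.146).

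Mitochondrial genes, the subject named in the title, shifted little. Genes encoded in mitochondrial DNA had a median log2 fold change of 0.21 (camera adjusted p = 0.0162), complex I genes 0.10 (camera adjusted p = 0.0126) and genes of complexes II to V 0.10 (camera adjusted p = 0.00428); all 3 had adjusted p = 0.829 with an estimated correlation. ND1 was 2676 ± 185 CPM in injury and 3169 ± 530.1 in conduit, and conduit sample 2, in which muscle genes were abundant, held the highest level at 3725 CPM. The call for mitochondrial DNA was lost without injury sample 1 (median 0.14), injury sample 2 (0.07) or conduit sample 2 (0.03). The calls for complex I and for complexes II to V were lost without injury sample 2 (medians -0.01 and 0.00), conduit sample 2 (0.06 and 0.07) or conduit sample 3 (0.05 and 0.06), and the medians were 0.22 and 0.23 without injury sample 1 and 0.19 and 0.20 without conduit sample 1. Without injury samples 2 and 3 both lists were called lower in conduit (-0.12 and -0.11). Within batch 2 the medians were -0.09, -0.09 and -0.08. Ppargc1a, a regulator of mitochondrial biogenesis, was 17.5 ± 0.584 CPM in injury and 19.6 ± 1.23 in conduit, and Tfam, which packages mitochondrial DNA, was 17.97 ± 1.395 CPM in injury and 19.7 ± 1.39 in conduit. The lists for biogenesis and dynamics, the TCA cycle, the mitochondrial ribosome and glycolysis had medians of 0.04, 0.07, 0.05 and 0.03, with camera adjusted p = 0.291, 0.174, 0.212 and 0.548. These medians within batch 2 were -0.04, -0.11, -0.08 and -0.14. All 4 lists were called without conduit sample 1 (0.09, 0.14, 0.15 and 0.10), and the mitochondrial ribosome also without injury sample 1 (0.18). The lowest medians with 1 library left out were 0.0029, -0.0037, -0.034 and -0.020 for these lists in the same order.

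Oxygen and oxidant responses did not pass as lists. The hypoxia response had a median of 0.06 (camera adjusted p = 0.243). Hif1a, the oxygen-sensing transcription factor, was 80.1 ± 3.35 CPM in injury and 79.2 ± 3.56 in conduit, and Vegfa was 53.8 ± 19.2 CPM in injury and 56.95 ± 27.6 in conduit. P4ha1, a collagen prolyl hydroxylase, was 58.6 ± 1.44 CPM in injury and 79.7 ± 3.295 in conduit. Antioxidant genes had a median of -0.01 (camera adjusted p = 0.284). Sod2 was 213 ± 6.62 CPM in injury and 223 ± 8.05 in conduit and Hmox1 was 11.99 ± 2.801 CPM in injury and 9.39 ± 2.25 in conduit. Nociceptor genes had a median of -0.06 (camera adjusted p = 0.168; within batch 2 -0.17). They were called lower in 7 of 19 tested alternatives, among them without injury sample 2 (-0.09) or conduit sample 3 (-0.17). Of 29 members 22 were lower, 5 of them with no overlap between groups, as were 696 of all 16478 genes. None of the 29 had an unadjusted edgeR p under 0.05. The sodium channel gene Scn9a was 239 ± 20.9 CPM in injury and 239 ± 20.4 in conduit and Calca, which encodes the peptide CGRP, was 429 ± 77.1 CPM in injury and 445 ± 87.3 in conduit. Axon injury genes had a median of -0.10 (camera adjusted p = 0.284), which ranged from -0.13 to -0.0069 with each library left out. Camera called the list in 2 of 19 alternatives. Like the erythroid, myelin and clock lists, this list passed fry's test for change in either direction, here at adjusted p = 0.00494. Atf3, induced by axon damage, was 14.7 ± 3.196 CPM in injury and 11.1 ± 0.26 in conduit, and Gal was 5.54 ± 1.38 CPM in injury and 6.04 ± 1.55 in conduit. Npy stood at 8.33, 52.2 and 56.9 CPM in injury and 3.72 to 5.65 in conduit. Crh, which encodes corticotropin-releasing hormone, was 0.032 ± 0.0369 CPM in injury and 0.542 ± 0.179 in conduit, with no injury library above 3 counts. Over all genes edgeR called 0 members of this list, with 2 higher and 3 lower at an unadjusted p under 0.05.

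Circadian clock genes fell as a list (median -0.28; camera adjusted p = 0.00229; adjusted p = 0.672 with an estimated correlation), with members on both sides. Nr1d1, a clock repressor, was 69.4 ± 8.33 CPM in injury and 22.3 ± 6.04 in conduit, and Dbp was 69.7 ± 20.2 CPM in injury and 25.03 ± 2.65 in conduit. Bmal1, which works in the opposite phase, was 10.1 ± 2.94 CPM in injury and 19.5 ± 2.25 in conduit. On the list, 5 members lower and 2 higher passed when adjusted over the list alone. The call was lost without conduit sample 3 (median -0.19), the median was -0.14 without injury sample 1, and within batch 2 the median was 0.04. Immediate early and heat shock genes had a median of -0.07 and a mean of -0.38 (camera adjusted p = 0.00428; adjusted p = 0.648 with an estimated correlation), a call lost without injury sample 2 (median -0.05; within batch 2 -0.02), and Fosb was 22.3 ± 19.8 CPM in injury and 2.86 ± 2.61 in conduit. Their median was -0.12 without injury sample 1, -0.14 without injury sample 3, -0.01 without conduit sample 2 and -0.12 without conduit sample 3. Unfolded protein response genes had a median of 0.19 (camera adjusted p = 0.00483; adjusted p = 0.672 with an estimated correlation). The chaperone Calr was 397 ± 29.97 CPM in injury and 523 ± 41.7 in conduit. Extracellular matrix genes had a median of 0.17 (camera adjusted p = 0.00754) and endothelial genes 0.15 (camera adjusted p = 0.0162), both with adjusted p = 0.829 with an estimated correlation. Col4a1, a basement membrane collagen, was 417 ± 24.5 CPM in injury and 556 ± 29.996 in conduit. The unfolded protein call was lost without injury sample 2 (median 0.15), injury sample 3 (0.14) or conduit sample 3 (0.14), and the median was 0.29 without injury sample 1. The matrix call was lost without injury sample 1 (-0.03), injury sample 3 (0.11) or conduit sample 1 (-0.02), and the endothelial call without injury sample 1 (0.08), conduit sample 1 (0.06) or conduit sample 2 (0.11). The matrix median was 0.41 without injury sample 2 and 0.34 without conduit sample 3, where the endothelial median was 0.26. Within batch 2 the unfolded protein, matrix and endothelial medians were 0.13, 0.69 and 0.22.

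Markers of neighbouring tissues set some libraries apart. Injury sample 1 held Gh1, pituitary growth hormone, at 4869 CPM against 0.452 to 15.3 in the other libraries, and Prl at 954 CPM. Conduit sample 2 held Acta1, skeletal muscle actin, at 2198 CPM and Myh4 at 1830.0 CPM, against 77.3 and 123 in injury sample 1. The skeletal muscle list was higher in conduit (median 4.01; camera adjusted p = 0.00119; adjusted p = 0.829 with an estimated correlation), and without conduit sample 2 the list was called lower, with a median of -3.67. Without injury sample 3 (3.52) it was not called, without injury sample 1 the median was 8.27, and within batch 2 the median was 0.41. Mobp, a myelin gene of the central nervous system, stood at 260.2, 112 and 511 CPM in injury and 484, 25.3 and 54.5 in conduit, highest in both libraries of batch 2. The central nervous system list had a median of -0.33 (camera adjusted p = 0.00505; adjusted p = 0.672 with an estimated correlation), a call lost without injury sample 1 (-0.38), injury sample 3 (-0.04), conduit sample 2 (-0.05) or conduit sample 3 (-0.13), and the median was -0.59 without injury sample 2 and -1.45 without conduit sample 1. Within batch 2 the median was -0.02.

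**Figure D3:**
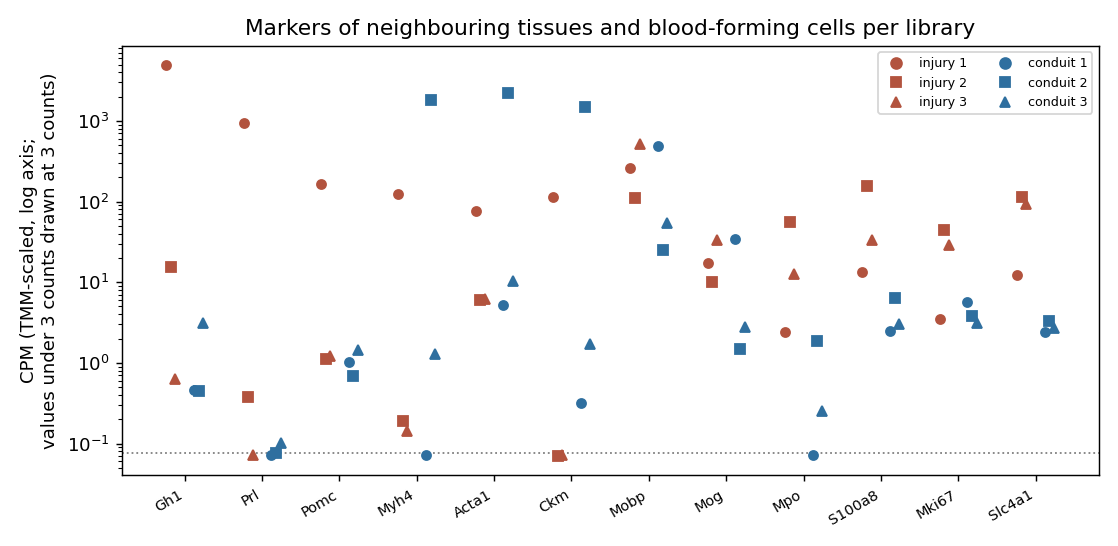
CPM of 12 marker genes in each library on a log axis, with values under 3 counts drawn at the level of 3 counts and a dotted line at the highest such level. Each point is 1 library; pituitary genes stand out in injury sample 1, muscle genes in conduit sample 2, and neutrophil and dividing-cell genes in injury samples 2 and 3.

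The remaining lists did not pass with all libraries. Lymphocyte genes had a median of -0.36, cholesterol synthesis 0.07, fibroblast and meninges 0.08, mural cell 0.14, adipocyte -0.03, pan-sensory and large-diameter neurons 0.01, potassium and HCN channels -0.02, apoptosis -0.02 and cytosolic ribosome -0.01, with camera adjusted p from 0.0898 to 0.786. The medians within batch 2 were, in the same order, 0.29, 0.03, 0.89, 0.35, -1.88, -0.12, -0.15, 0.04 and 0.04. Adipocyte genes were called without conduit sample 2 (-2.28), the library in which Adipoq, a fat cell hormone, had 310 counts against 2 and 12 in the other conduit libraries and 44, 166 and 166 in injury. Lymphocyte genes were called without injury sample 1 (-0.21), injury sample 3 (-0.32) or conduit sample 1 (-0.56), fibroblast and meninges genes without conduit sample 1 (-0.28), conduit sample 2 (0.29) or conduit sample 3 (0.38), and mural cell genes without injury sample 2 (0.43) or conduit sample 3 (0.40). The lowest mural cell median with 1 library left out was -0.16. Cholesterol synthesis was called without conduit sample 2 (0.14), the pan-sensory list without conduit sample 1 (0.11), and the cytosolic ribosome without injury sample 1 (0.12) or injury sample 2 (-0.08). In all, 17 of 37 tested lists passed with a preset correlation, 10 higher and 7 lower in conduit, and 1 passed with an estimated correlation. The batches overlap in 1 library of each group and the labelled days, if they are true days, separate the groups completely, so neither can be told apart from the treatment. The edgeR fit with batch as a term takes the group difference from batch 2 alone, which holds 1 library of each group. In that fit RGD1563601 had a log2 fold change of -2.74 and was not called. The erythroid, interferon and myelin lists were called, and their medians of -3.18, 1.08 and 0.37 nearly repeat those within batch 2. With this term 0 genes passed and 257 had an unadjusted p under 0.05.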

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

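Leaving out a pair of libraries, sample weights, testing without the tissue lists and the lists within batch 2 were chosen only after the results were seen. The erythroid, interferon and myelin lists were called in the same direction under all 19 tested alternatives with the preset correlation, with medians of -3.70 to -2.47, 0.76 to 2.37 and 0.31 to 0.50. In the fit over all libraries camera gave adjusted p = 0.0246, 0.383 and 0.423 with an estimated correlation, so only the erythroid call held there. RGD1563601 was lower under every alternative (log2 fold change -2.74 to -2.28) and passed in 16 of 22. Over all lists and alternatives, 592 outcomes counted as the same. These were calls kept in direction, lists called in neither fit whatever their direction, and values within batch 2 that stayed within the spread. Another 51 lost the call and 57 gained one without a turn, and 27 turned direction with a call in at least 1 of the settings compared. Within batch 2, 12 values moved by more than the spread.

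Against 1 gene, lower in conduit, the genes called were 6 (1 higher, 5 lower) with no filter, 208 (111 higher, 97 lower) with DESeq2, 8 (2 higher, 6 lower) with limma on log2 FPKM and a pseudocount of 1, 5 (0 higher, 5 lower) with 0.1, 3 (1 higher, 2 lower) with 1 and no filter, and 366 (123 higher, 243 lower) at an unadjusted p and a fold of at least 2, a looser threshold by construction. They were 13 (0 higher, 13 lower) without injury sample 1 and conduit sample 2, 23 (14 higher, 9 lower) without injury samples 2 and 3, where the lone injury library is assumed to vary like the conduit group, and 15 (4 higher, 11 lower) with sample weights. With the batch or the day in the edgeR fit they were 0 (0 higher, 0 lower) and 0 (0 higher, 0 lower), with 257 and 330 genes at an unadjusted p under 0.05; the labelled days may not be true sampling days. No sample correlated best with the sample of its own number, and with the number as a block 1 call became 0 (0 higher, 0 lower; 554 unadjusted). Leaving out each library in turn gave 0 to 38 genes, 0 to 31 higher and 0 to 37 lower. Lists called were 1 with camera at an estimated correlation and 1 with fry, and 15 to 22 with each library left out. The cause was not tested where none is given.

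Some lists reversed, by the test's direction where the median kept its sign. With the batch in the fit the medians were -0.0907 for the mitochondrial-DNA-encoded list, -0.0903 for complex I, -0.0847 for complexes II to V, -0.12 for pan-sensory neurons and -0.0185 for immediate early and heat shock genes. With the day they were 0.00680 for mitochondrial DNA, -0.21 for pan-sensory neurons, -0.00920 for immediate early genes, 0.25 for the clock and 0.17 for the cytosolic ribosome. Within batch 2 they were -0.0906, -0.0902 and -0.0847 for the 3 respiratory lists and 0.0375 for the clock. The fit with batch takes the group difference from batch 2 alone, so its values nearly repeat those within batch 2. Without injury sample 1 and conduit sample 2 the cytosolic ribosome was at 0.13, and with sample weights at 0.0444. Without injury samples 2 and 3 complex I was at -0.12, complexes II to V at -0.11, the mitochondrial ribosome at -0.14, the unfolded protein response at 0.0110, proliferation at 0.0881 and skeletal muscle at 2.67. With each library left out the ranges were -0.0850 to 0.12 for the cytosolic ribosome, -0.00650 to 0.22 for complex I, 0.00101 to 0.23 for complexes II to V, -0.28 to 0.38 for fibroblast and meninges and -3.67 to 8.27 for skeletal muscle. The cause was not tested for any of these.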

Other observations

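The genes of this paragraph come from the naming rule. Counts over splits of the libraries and leaving out 1 library were fixed beforehand, and the other tests that weigh an explanation below were chosen only after the result was seen. Complement C1qc, made by macrophages, was 15.6 ± 2.59 CPM in injury and 28.8 ± 10.98 in conduit, and RT1-Ba, a class II gene, was 4.22 ± 2.52 CPM in injury and 12.1 ± 6.12 in conduit. Cd79b, a part of the B cell receptor, stood at 0.124, 4.801 and 2.39 CPM in injury and 0.29, 0.402 and 0.126 in conduit, so only injury samples 2 and 3 were higher. Lss, an enzyme of cholesterol synthesis, was 122 ± 2.56 CPM in injury and 83.1 ± 15.6 in conduit, and Igfbp6, a growth factor binding protein, was 32.95 ± 12.3 CPM in injury and 76.8 ± 13.3 in conduit. None of these passed the edgeR threshold over all genes.

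The libraries can be parted into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1 gene and the highest of the others 3, and 2 of 10 splits gave as many as the real one. The split with 3 genes set injury samples 1 and 3 and conduit sample 3 against the rest and had 2744 genes at an unadjusted p under 0.05, which points to a structure of the samples other than the treatment. For lists with the preset correlation the real split gave 17 and the highest of the others 24, and 9 of 10 splits gave as many, so a count of called lists of this size came with most groupings of these libraries. The real split and the split of injury samples 1 and 2 and conduit sample 1 against the rest follow batch alike, since both keep batches 1 and 3 apart and divide batch 2. The latter gave 22 lists and 0 genes (234 at an unadjusted edgeR p under 0.05). Its medians had sizes of 0.47 for interferon, 0.10 for myelin and 0.69 for erythroid. It differs from the real split only in the 1 library of each group in batch 2, so this does not settle the part of batch. With an estimated correlation the real split gave 1 list, erythroid, and each other split 0. The size of the real median was 1.52 for interferon against 1.02 in the highest other split, 0.40 against 0.28 for myelin and 3.40 against 1.31 for erythroid. These lists were singled out for their shift in the real split, so its first rank is no separate support. With injury samples 1 and 2 and conduit sample 2 against the rest, camera at the preset correlation gave adjusted p = 3.5e-37 for interferon and 4.7e-12 for myelin.

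Interferon genes were higher in conduit, which may reflect the treatment, more immune cells or the batch. Without conduit sample 1 the macrophage median was -0.26, with an upper end of its 95% bootstrap interval of -0.0163, below the interferon interval of 1.02 to 1.62. The bootstrap drew list members, which are correlated, so these intervals carry no spread between libraries. Mean macrophage log2 CPM was 3.15 and 2.79 in conduit samples 2 and 3 against 2.94, 3.64 and 3.11 in injury. Mean interferon log2 CPM was 5.49 and 5.41 against 3.39, 3.39 and 4.93. These levels argue against more macrophages as the whole source in conduit samples 2 and 3. Within batch 2 the macrophage difference was 0.95 and the interferon difference 1.08 between 1 library of each group, so more macrophages in conduit sample 1 stay open. Lymphocyte medians ranged from -0.62 to 0.89 over the alternatives and leave these cells open too. The batch cannot be told apart from the treatment, nor can the labelled day if it is a true one.

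Red cell and marrow genes were lower in conduit, which may reflect bone marrow taken with some injury ganglia, more blood in the injury samples or the treatment. Injury sample 1 lay at -0.34 against the highest conduit library for proliferation and at -0.83 for neutrophil genes, of which 7 of 18 were lower in every conduit library than there; marrow was thought of from these same lists, so this decides nothing, and without injury samples 2 and 3 the erythroid median was -2.47. The 7 tested hemoglobin genes other than Hba-a3 were lower in every conduit library. Their fold changes differed by up to 3.22 standard errors, past the bound of 2 set for a single common fall. Without Hbq1b, which had fewer than 10 counts in every conduit library, they differed by up to 1.96. The largest difference over all gene pairs can pass that bound under a common fall, and the standard errors treat the genes as independent. More red cells therefore stay open. At the fall of Hbq1b and from its own lowest injury library Hba-a3 would have 152 counts in conduit, against 1 seen (95% Poisson upper limit 5.57, which covers counting error only), and this argues against red cells alone for that gene. A difference in genotype, reads shared between copies and the treatment stay open.

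Clock genes moved in opposite directions, which may reflect the time of day of collection, neighbouring tissue or the treatment. With 5 genes of one phase and 10 of the opposite phase, assigned from their known phase after the values were seen, the difference between phases was -2.26 ± 0.42 in injury and -0.90 ± 0.04 in conduit (n = 3; exact permutation p = 0.1, the smallest it can give). Without injury sample 1 and conduit sample 2 the groups differed by 1.14, more than the largest range within a group of 0.84, which argues against the tissue in those libraries as the whole source. That comparison keeps injury samples 2 and 3, where neutrophil, dividing-cell and bone genes were highest, so tissue in those samples stays open. Over all libraries the groups differed by 1.36 and within batch 2 by 0.94. Collection times are not given in the sources used here, so time of day cannot be told apart from the treatment.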
